A study of Mus musculus with 8 samples.

How the data were processed

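Regulatory T cells (Tregs, the Foxp3-expressing CD4 T cells that restrain immune responses) were sorted by flow cytometry from muscle and spleen of male C57BL/6 mice, per the labels' protocols. The mice were 2 months old or older than 6 months, and muscle had been injured 4 days before with cardiotoxin, a snake venom toxin that destroys muscle fibres, at 0.9 µg per muscle. Each library came from 1500 sorted cells, whose RNA was amplified by in vitro transcription before library PCR, per the labels' protocols. Such amplification copies some transcripts more than others and no molecular identifiers are described, so a count is a count of reads and not of molecules. The 8 libraries form 4 groups of 2: young spleen, aged spleen, young muscle and aged muscle. The series' design text calls the 2 libraries of a group biological duplicates but does not say whether they came from separate animals or pools, so p-values measure only the spread between these libraries.

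The authors deposited 1 table of whole-number read counts per gene, 38406 gene symbols by 8 libraries, with no normalization. The submitters' processing notes name TopHat2, TopHat, Picard, SAMtools 0.1.19 and HTSeq and the mouse build mm10. The annotation and the strand setting are not given in the sources used here. Reads of near-identical genes such as Hspa1a and Hspa1b or the alpha globins can be split or dropped by such counting, and reads of overlapping or antisense genes such as Xist cannot be assigned with confidence. All 13 genes encoded by the mitochondrial genome were at 0 in every library, so their list was not tested. Every column was used and every row named a gene. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, counted from 1. Of 308 symbols that the naming rule gave, 303 matched 1 annotated gene.

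Totals ranged from 1969982 to 4008622 counts per library. At that depth 3 counts, the limit that a count of 0 allows, correspond to 0.43 to 0.67 CPM over the 2 libraries of a group, and such floors and counting intervals cover counting error only. Differential expression was computed in R 4.3.3 with edgeR 4.0.16 on the deposited counts. Genes were kept by filterByExpr with the 4 groups (14772 genes), libraries were scaled by TMM, and 1 quasi-likelihood model with a coefficient per group was fitted robustly to all 8 libraries, so that the groups shared 1 estimate of the spread with 4 residual degrees of freedom. The biological coefficient of variation was 0.288. The contrasts, tested two-sided with Benjamini-Hochberg adjustment at 0.05, were age in muscle, age in spleen, the difference of these age effects, and muscle against spleen at each age. Every adjusted p of a gene is from this test unless another is named, and a standard error is the log2 fold change divided by the square root of its F statistic. CPM values are counts scaled by the TMM-adjusted library size, given as mean ± SD of 2 libraries. Logged CPM used a prior count of 2.

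The 25 gene lists were fixed before the data were examined, covering Treg identity and function, homing, signalling, cell cycle, metabolism, interferon response and markers of other cell types. Of these, 24 had at least 3 measured members and were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run as checks. The genes named in the text follow a rule fixed at the same time. It takes, per comparison and direction, the 12 largest fold changes among genes past the threshold with a mean of at least 4 on the log2 CPM scale and no overlap between the libraries of the groups compared (no such condition for the difference of age effects). It leaves out predicted and clone-named genes, ribosomal protein pseudogenes and antigen-receptor segments. It adds the 4 members of smallest p in each list and 10 identity genes in the comparisons that involve muscle. The text gives a part of these genes. The rule's examples of clone names did not include names starting with AC or RP. Treating these as clone names was decided after the values were seen, and it left out 2 genes in 4 places. AC137902.1 had log2 fold changes of -2.89 for age in muscle, -3.83 for the difference of age effects and 4.30 for tissue in young mice, and RP23-159J2.2 had -2.40 for age in muscle.

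The pipeline was tested on simulated data drawn from the real means, library sizes and dispersions, with 200 of 14772 genes changed. Each gene had 1 mean over all libraries and 1 dispersion for all groups, and genes were drawn independently. A larger spread in muscle, a deviating library and correlation between genes were not simulated, so error and recovery in the real data may be worse. For age in muscle it recovered 19.4% of 2-fold, 52.2% of 4-fold and 71.2% of 8-fold changes, with 11 calls among 14521 unchanged genes. For age in spleen the shares were 19.4%, 59.7% and 74.2%, and for the difference of age effects 8.96%, 31.3% and 60.6%. A gene that did not pass may therefore still have changed. Alternatives were other normalization factors, no filter or a mean of at least 10 CPM, DESeq2 1.42.0, replicate number as a block, only the 2 groups compared, and each library left out in turn, where the lone library was assumed to vary like the others. The filter follows the smallest group, so leaving out a library raised the number of genes tested to between 15836 and 16728. The same refits on the 14772 genes, and on list members without young muscle replicate 1 or aged muscle replicate 2, were added after seeing the data. Scaling by library size alone, list counts without young muscle replicate 1 or aged muscle replicate 2, and counts of list members at an unadjusted p or by DESeq2 were added after seeing the data.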

Results

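The data are RNA read counts of sorted Tregs from injured muscle and from spleen of young and aged mice, with 2 libraries in each of 4 groups. Young spleen libraries held 2375505 and 2798590 counts, aged spleen 4008622 and 2876160, young muscle 2608695 and 1969982, and aged muscle 2616638 and 2148765. Spearman correlations between the 2 libraries of a group, across genes, were 0.965 in young spleen and 0.967 in aged spleen. In young muscle the value was 0.893 and in aged muscle 0.920, against 0.765 to 0.941 between libraries of different groups. Young muscle replicate 2 correlated at 0.921 and 0.906 with aged muscle replicates 1 and 2, above 0.893 with its own replicate. By this measure the muscle libraries did not group by age. Counts of every replicate pair differed by more than sampling noise, with a chi-square per gene of 3.83 to 8.61. The first principal component held 50.9% of the variance and separated spleen from muscle. The second held 15.2% and set young muscle replicate 1 apart, at -87.9 against -11.0 for replicate 2. The first also nearly followed the number of genes found after thinning each library at random to 1969982 counts. That number was 16638 and 17056 in young spleen, 18608 and 18199 in aged spleen, 18124 and 19361 in young muscle, and 19201 and 21114 in aged muscle. Whether the component reflects tissue or this number was not tested. The Treg transcription factor Foxp3 (chromosome X, 7573644 to 7595245) was read at 20.1 ± 6.6 CPM in young spleen, 20.7 ± 7.1 in aged spleen, 33.0 ± 12 in young muscle and 32 ± 12 in aged muscle (SD, n = 2).

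**Figure D1:**
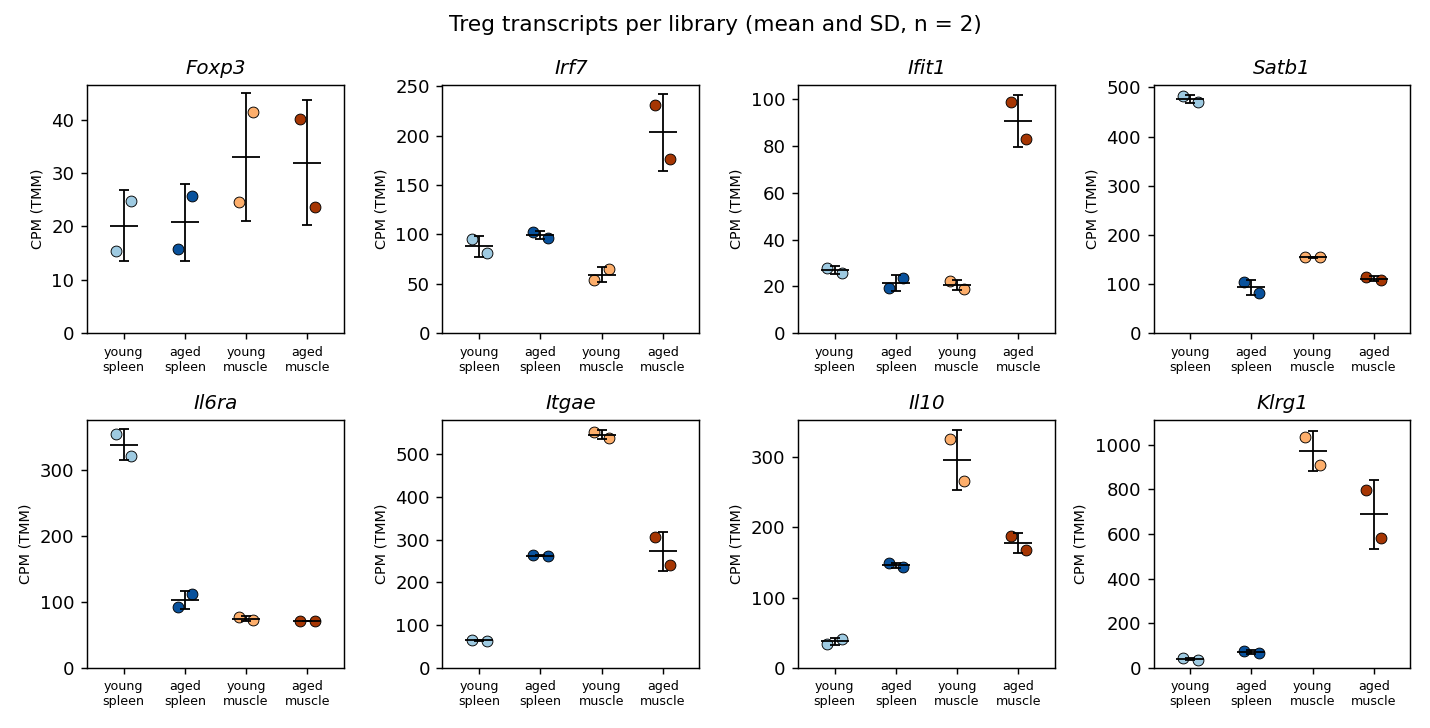
Normalised read counts (CPM after TMM scaling, linear axes from 0) of 8 genes in each of the 8 libraries, with points for libraries and bars for the mean and SD of 2 libraries. Irf7 and Ifit1 were highest in both aged muscle libraries, Satb1 and Il6ra in both young spleen libraries, and Foxp3 spanned 20.1 to 33.0 CPM over the group means.

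The comparison of aged with young muscle addressed how age alters Tregs that have entered injured muscle. Genes of the interferon response rose together: 29 of 52 measured members rose and 0 fell by edgeR, 32 and 0 by DESeq2 and 43 and 1 at an unadjusted p under 0.05. Adjusted over the list alone 43 rose and 1 fell. Irf7, a transcription factor that drives interferon production (chromosome 7, 141262706 to 141266481), rose from 59.2 ± 7.4 to 203 ± 39 CPM, a log2 fold change of 1.78 ± 0.20 (SE; edgeR adjusted p = 0.00022). The interferon-inducible GTPase gene Iigp1 rose by 2.46 ± 0.29 and the antiviral gene Ifit1 by 2.14 ± 0.28. The median of the list was 1.08 and its camera adjusted p was 1.59e-42, with adjusted p = 0.14 with an estimated correlation and 0.018 by fry. Without young muscle replicate 1, 16 members rose, or 15 with the tested genes held. Irf7, Iigp1 and Ifit1 kept their calls under every alternative run.

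Of 17 measured Treg identity genes, 2 rose and 2 fell with age in muscle, and the list did not pass camera (adjusted p = 0.446), although it did without aged muscle replicate 2 (adjusted p = 0.014; range over the libraries left out up to 0.92). Itgae, which encodes the CD103 integrin chain, fell from 545 ± 10 to 272 ± 46 CPM (SD, n = 2; edgeR adjusted p = 0.0028). The inhibitory receptor gene Ctla4 fell by 0.81 ± 0.14, while the transcription factor genes Ikzf4 and Ikzf2 rose by 0.89 ± 0.17 and 0.73 ± 0.15. Of 22 tissue Treg genes, 2 rose and 4 fell, and the list passed camera only without aged muscle replicate 1. The growth factor gene Areg rose by 1.19 ± 0.23 and Dgat2 by 1.56 ± 0.29, and the chemokine receptor genes Ccr3 and Cxcr6 had log2 fold changes of -1.24 ± 0.20 and -1.66 ± 0.33. Foxp3 differed by -0.04 ± 0.40 (edgeR adjusted p = 0.98), Il2ra by -0.04, Klrg1 by -0.50 and Gata3 by 0.30, none past the threshold. Il1rl1, which encodes the IL-33 receptor, was at 124 ± 18 CPM in young and 195 ± 51 in aged muscle, a difference of 0.66 ± 0.22 that did not pass (edgeR adjusted p = 0.15). Calls ended for Areg (0.98) and Dgat2 (1.36) without aged muscle replicate 1, for Ikzf4 (0.79) without young muscle replicate 1, for Cxcr6 without young muscle replicate 1 (-1.54) or aged muscle replicate 2 (-1.59), and for Ikzf2 without young muscle replicate 1 (0.65) or any 1 spleen library (0.71). That of Cxcr6 also ended without aged muscle replicate 1 with the tested genes held (-1.73). That of Klrg1 was gained without aged muscle replicate 1 (-0.78), and fitting only the 2 groups compared ended every call in this paragraph. By edgeR and by DESeq2, 0 of 41 G1/S and 0 of 50 G2/M genes passed, with 1 and 4 at an unadjusted p under 0.05, and the G2/M list passed camera only without young muscle replicate 2. Mki67 was at 50.3 CPM in both groups.

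Among 25 homing genes, 2 rose and 4 fell in aged muscle. The integrin gene Itga4 rose by 1.99 ± 0.23. The chemokine gene Ccl5 rose by 1.74 ± 0.26, from 82.2 ± 32 to 277 ± 17 CPM. The proprotein convertase gene Furin had a log2 fold change of -1.03 ± 0.18, the early gene Nr4a2 1.55 ± 0.19 and the small heat shock protein gene Hspb1 -2.72 ± 0.46. The call of Furin ended without young muscle replicate 1 (-0.83), and those of Itga4, Ccl5, Furin, Hspb1 and Sall3 with only the 2 groups compared. The largest rises under the naming rule were of Gatm at 3.88, Kazald1 at 3.75, Smco1 at 3.63 and Kit at 3.23. The largest falls under that rule were of Cd40lg, the CD40 ligand gene (chromosome X, 57212143 to 57224042), at -5.60 ± 0.42 and from 251 ± 78 to 4.99 ± 3.5 CPM, and of Sall3 at -3.60 and Nr5a2 at -2.95. Gatm, Kazald1, Kit, Sall3 and Nr5a2 were each high in both libraries of 1 group alone, a pattern taken up below whose cause stays open.

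Markers of myeloid cells, which a Treg sort would be meant to exclude, differed between these groups: 2 of 24 fell with age (4 by DESeq2 and 12 at an unadjusted p under 0.05), with a list median of -2.90 (camera adjusted p = 3.76e-07, adjusted p = 0.76 with an estimated correlation). Fcer1g, a signalling chain of Fc receptors, had 115 counts in young and 2 in aged muscle, a ratio of 64.7 (95% counting interval 17.5 to 541). The 115 counts were 99 in young muscle replicate 1 and 16 in replicate 2, a spread that the interval leaves out. Tyrobp had a log2 fold change of -4.86 ± 0.96. Without young muscle replicate 1 the list had a median of 0.05 and its call ended. The calls of Fcer1g and Tyrobp ended too, though their log2 fold changes remained at -4.17 and -2.51. The call of Fcer1g also ended without aged muscle replicate 1, and that of Tyrobp without any 1 spleen library (-4.87 to -4.88) or either aged muscle library (-5.56 and -4.44). Ribosomal protein genes had a median of -0.30, with 2 of 78 falling by edgeR, 16 by DESeq2 and 33 at an unadjusted p under 0.05. By edgeR 0 fell without young muscle replicate 1 or aged muscle replicate 2, and the list had adjusted p = 0.76 with an estimated correlation. The oxidative phosphorylation list passed camera (median -0.22) with 0 of 74 members called by edgeR or DESeq2, 8 lower at an unadjusted p under 0.05, and adjusted p = 0.84 with an estimated correlation. It did not pass without young muscle replicate 1 or aged muscle replicate 2.

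In total 168 genes were higher and 130 lower in aged muscle, with 2258 at an unadjusted p under 0.05. Fitting only these 2 groups left 33 higher and 17 lower, and fitting all genes with a count gave 417 and 331. DESeq2 gave 243 higher and 254 lower, and library-size scaling 225 and 114. The counts were 102 and 52 without young muscle replicate 1, 586 and 481 without replicate 2, 169 and 275 without aged muscle replicate 1, 125 and 51 without replicate 2, and 110 to 122 higher and 72 to 77 lower without any 1 spleen library. Leaving out a library also raised the number of genes tested, to between 15836 and 16728. With the 14772 genes held, the counts were 98 and 49 without young muscle replicate 1, 553 and 425 without replicate 2, 156 and 205 without aged muscle replicate 1, 123 and 46 without replicate 2, and 102 to 111 higher and 67 to 70 lower without any 1 spleen library.

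The same age contrast in spleen addressed whether Tregs outside muscle change with age. Genes of naive and lymphoid-resident T cells fell, 13 of 18 by edgeR and by DESeq2 and 14 at an unadjusted p under 0.05. By each of these 0 rose. Satb1, a chromatin organiser (chromosome 17, 51736187 to 51833290), fell from 477 ± 8.2 to 93.1 ± 15 CPM (log2 fold change -2.35 ± 0.17, edgeR adjusted p = 2.4e-06). The receptor gene Il6ra fell by 1.73 ± 0.17 and the transcription factor gene Foxp1 by 1.22 ± 0.14. The list median was -1.28 (camera adjusted p = 1.09e-36) and its call held with an estimated correlation (adjusted p = 0.0037).

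Genes typical of tissue Tregs rose in aged spleen, 9 of 22 with 0 falling by edgeR or DESeq2 and 1 at an unadjusted p under 0.05 (median 0.91, camera adjusted p = 2.9e-13, adjusted p = 0.11 with an estimated correlation). The cytokine gene Il10 rose from 37.8 ± 5.2 to 146 ± 4.0 CPM (log2 fold change 1.94 ± 0.19, edgeR adjusted p = 3.3e-05), Areg by 2.11 ± 0.27, Batf by 1.04 ± 0.18 and Prdm1 by 1.31 ± 0.25. Of 20 effector and co-inhibitory receptor genes 7 rose, among them Tnfrsf4 by 1.15 ± 0.15, Tnfrsf9 by 1.19 ± 0.18 and Pdcd1 by 1.57 ± 0.25 (adjusted p = 0.17 with an estimated correlation). Among 14 genes of the IL-1 receptor family 4 rose, Il1r2 by 3.37 ± 0.29, Il18r1 by 2.04 ± 0.23, Il1r1 by 4.43 ± 0.58 and Il18rap by 2.00 ± 0.38 (adjusted p = 0.11 with an estimated correlation). Of the Treg identity genes 5 rose and 2 fell, Itgae rising by 2.04 ± 0.17 and the IL-2 receptor gene Il2ra with a log2 fold change of -0.91 ± 0.15 (adjusted p = 0.36 with an estimated correlation). Calls ended without young spleen replicate 1 for Batf (0.99), Prdm1 (1.26), Pdcd1 (1.30) and Il18rap (1.81), and without young spleen replicate 2 for Batf (1.11), Prdm1 (1.39), Tnfrsf9 (0.99) and Il2ra (-0.83). They ended without aged spleen replicate 1 for Prdm1 (1.14) and Il2ra (-0.85), and without aged spleen replicate 2 for Batf (1.04), Il18rap (1.62) and Il2ra (-0.95). Further calls ended with the tested genes held, for Batf without aged spleen replicate 1 (1.05), Il18rap without young spleen replicate 2 (2.27) and Pdcd1 without aged spleen replicate 2 (1.39).

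Ribosomal protein genes fell in aged spleen, 38 of 78 by edgeR, 57 by DESeq2 and 65 at an unadjusted p under 0.05, with a median of -0.54 that was -0.37 under library-size scaling (adjusted p = 0.36 with an estimated correlation). They made up 18.2 and 17.3% of counts in young spleen and 13.6 and 13.2% in aged spleen. Aged spleen also gave more genes at equal depth than young spleen, and a link between the 2 was not tested. How many of the 38 kept their call without a spleen library was not counted, and calls over all genes were then far fewer. Of 28 lipid synthesis genes 2 fell, among them Srebf2 by 0.62 ± 0.16 (adjusted p = 0.36 with an estimated correlation), and of 13 helper lineage genes 2 rose, Ccl5 by 1.93 ± 0.27 and Cxcr3 by 1.03 ± 0.21 (adjusted p = 0.20 with an estimated correlation). The call of Srebf2 ended without any 1 spleen library (-0.48 to -0.74) and with library-size scaling (-0.45), and that of Cxcr3 without young spleen replicate 1 (0.76), aged spleen replicate 1 (0.99) or replicate 2 (1.10). Erythroid markers passed camera with 0 of 11 members called by edgeR or DESeq2 and 1 at an unadjusted p under 0.05 (adjusted p = 0.45 with an estimated correlation). That list did not pass without young spleen replicate 2, aged spleen replicate 2 or aged muscle replicate 2. Of the 52 interferon genes 2 rose and 1 fell, with a median of 0.10 (camera adjusted p = 0.737). Under the naming rule, which sets a floor on expression, the largest rises were of Ccdc63 at 5.71, Tpte at 4.08 (not called without young spleen replicate 1, 4.06, nor without replicate 2 with the tested genes held) and Bzrap1 at 3.51, and the largest falls of Zic1 at -5.69, Smc1b at -4.89 and Fgd1 at -3.93. Ccdc63, Bzrap1, Zic1, Smc1b and Fgd1 also showed the pattern of genes high in both libraries of 1 group alone.

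Age in spleen gave 307 genes higher and 320 lower, with 2460 at an unadjusted p under 0.05. Library-size scaling moved the split from 49.0% to 67.4% higher (489 and 236), fitting only these 2 groups gave 928 and 1002, and no filter gave 632 and 407. Without 1 spleen library the counts were 82 to 104 higher and 62 to 81 lower, and without young muscle replicate 1 or 2 the higher counts were 588 and 596. With the tested genes held these were 74 to 88 higher and 60 to 81 lower, and 537 and 567 higher.

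**Figure D2:**
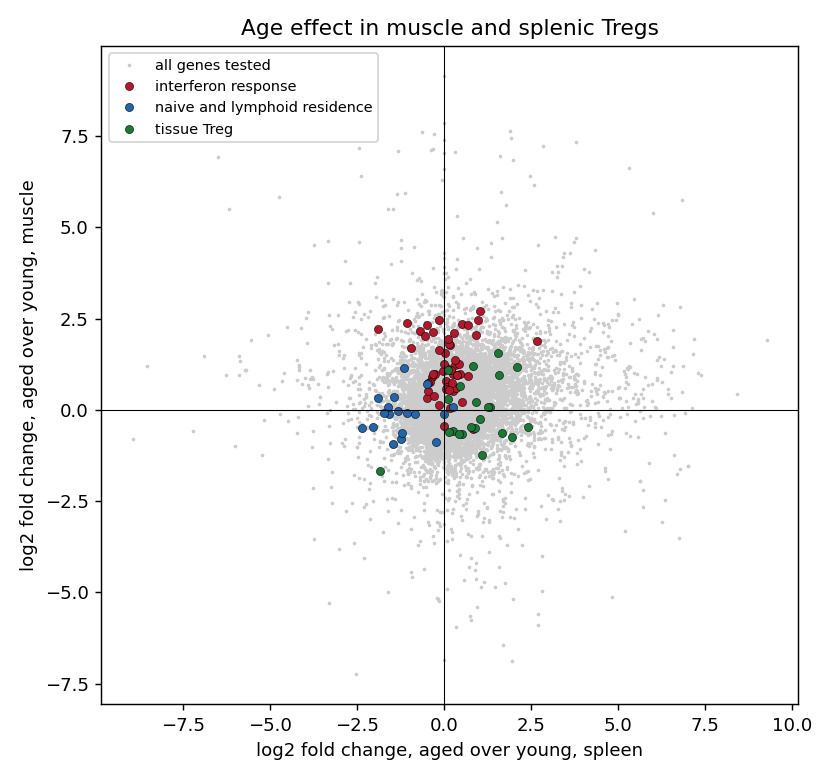
Log2 fold change with age in muscle (vertical axis) against that in spleen (horizontal axis), 1 point per tested gene, with 3 gene lists in colour. Interferon genes lie above 0 in muscle with a median of 1.08 and near 0 in spleen with a median of 0.10, while naive genes lie below 0 in spleen with a median of -1.28.

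The difference of the age effects was tested directly, as the change in muscle minus that in spleen. It was higher for 13 interferon genes and lower for 0 of 52, with Oas2 at 4.11 ± 0.58, Ifit1 at 2.46 ± 0.39 and Irf7 at 1.61 ± 0.28 (list median 1.09, adjusted p = 0.12 with an estimated correlation). It was higher for 9 of 18 naive genes, Satb1 at 1.87 ± 0.23 among them, a call that held with an estimated correlation (adjusted p = 0.017). The naive list did not rise with age in muscle (median -0.09, 0 rose and 2 fell), so its difference came from the fall in spleen (median -1.28). The difference was lower for 6 of 22 tissue Treg genes, with Il10 at -2.68 ± 0.26, Maf at -1.23 ± 0.23 and Batf at -1.30 ± 0.25 (adjusted p = 0.12 with an estimated correlation), and for Itgae at -3.04 ± 0.23 and Klrg1 at -1.39 ± 0.27. The calls of Batf without any 1 spleen library (-1.27 to -1.38), Maf without young spleen replicate 1 (-1.13) or either aged spleen library (-1.26 and -1.25), Klrg1 without young spleen replicate 2 (-1.28) or aged spleen replicate 1 (-1.29), and Irf7 without young spleen replicate 1 (1.46) or aged spleen replicate 2 (1.54) ended. That of Klrg1 also ended without young spleen replicate 1 with the tested genes held (-1.52). In all 199 genes had a higher and 173 a lower age effect in muscle, with 1920 at an unadjusted p under 0.05. Without filtering the counts were 299 and 371, without any 1 spleen library 82 to 90 and 77 to 81, and without young muscle replicate 2 the lower count was 391. With the tested genes held these were 71 to 88 and 66 to 72, and 348.

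Across the 14772 genes, which are not independent replicates, the age effects in the 2 tissues correlated with Pearson's r of 0.14 and Spearman's rho of 0.18, and 57.1% had the same sign. Pearson's r was -0.03 without aged muscle replicate 2 and 0.07 to 0.18 without any other library, or -0.01 and 0.08 to 0.20 with the tested genes held. The comparisons share no library, but they share the spread of each gene, which the numbers for independent lists below leave out. Genes higher with age in both tissues numbered 26 against 3.49 for independent lists, and 22 were higher in muscle and lower in spleen against 3.64. Lower in muscle and higher in spleen were 16 against 2.70, and lower in both 5 against 2.82 (Fisher's exact p = 0.21). Genes of opposite direction thus also exceeded the numbers for independent lists, so the overlap alone does not show a shared direction.

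Muscle against spleen within an age addressed what distinguishes Tregs of injured muscle from those of a lymphoid organ. In young mice 18 of 22 tissue Treg genes were higher in muscle and 0 lower. Ccr3, an eotaxin receptor (chromosome 9, 124021972 to 124031689), was at 2.10 ± 0.32 CPM in spleen and 197 ± 1.3 in muscle (log2 fold change 6.51 ± 0.30, edgeR adjusted p = 3.5e-09). The chemokine receptor gene Ccr2 was higher by 4.70 ± 0.19, the lectin-like receptor gene Klrg1 by 4.66 ± 0.21, Il1rl1 by 3.35 ± 0.27 and Areg by 3.02 ± 0.27. Of the naive genes 16 were lower in muscle and 2 higher, with Tcf7 at -4.38 ± 0.21, Lef1 at -2.96 ± 0.19 and Ccr7 at -3.04 ± 0.23. Both calls held with an estimated correlation (adjusted p = 0.025 and 0.005). In aged mice 12 tissue Treg genes were higher and 2 lower, with Ccr2 at 3.95 ± 0.18 and Klrg1 at 3.28 ± 0.19, and 11 naive genes were lower and 3 higher (adjusted p = 0.12 and 0.069 with an estimated correlation).

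Other genes with large differences at both ages were Gzmb, Lmna and Cdkn1a, higher in young muscle by 4.97 ± 0.43, 5.47 ± 0.26 and 5.26 ± 0.27 and in aged muscle by 4.90 ± 0.43, 5.24 ± 0.26 and 3.99 ± 0.23. They encode a cytotoxic protease, a nuclear lamina protein and a cell cycle inhibitor. The near-identical heat shock genes Hspa1a and Hspa1b, whose reads cannot be separated with confidence, were at -5.46 and -5.13 in young and -5.07 and -5.03 in aged muscle. Ctla4 was higher in muscle by 2.29 ± 0.14 in young and 1.28 ± 0.14 in aged mice. Ribosomal protein genes were lower in muscle, 67 of 78 in young and 50 of 78 in aged mice (adjusted p = 0.33 and 0.54 with an estimated correlation). Interferon genes were lower in young muscle than in young spleen, 16 against 1 higher, whereas in aged mice 14 were higher and 2 lower, with Ifit1 at 2.09 ± 0.27 (adjusted p = 0.33 and 0.54 with an estimated correlation). In aged mice the interferon list did not pass camera without aged muscle replicate 1. Myeloid markers were higher in young muscle for 9 of 24, and for 1 of 23 without young muscle replicate 1.

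**Figure D3:**
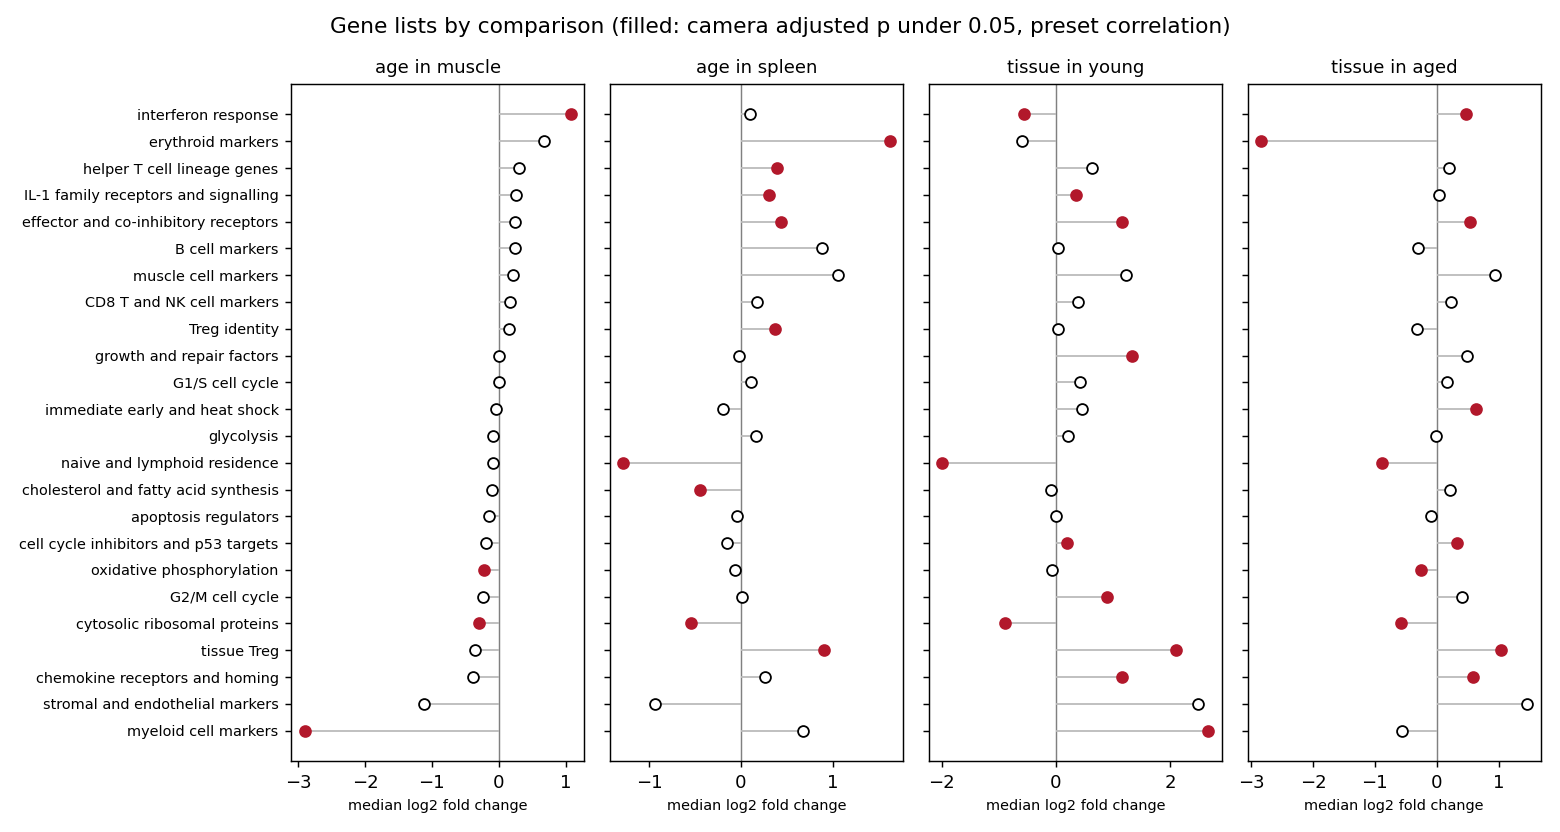
Median log2 fold change of 24 gene lists (rows) in 4 comparisons (panels, each with its own horizontal scale), filled where camera with the preset correlation passed at an adjusted p of 0.05. The naive list lies at -1.28 with age in spleen and -1.99 for tissue in young mice, and the myeloid list at -2.90 with age in muscle.

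Tissue in young mice gave 1681 genes higher and 1609 lower in muscle, and tissue in aged mice 1413 and 1370, with 5378 and 5094 at an unadjusted p under 0.05. The young counts were 675 and 808 without young spleen replicate 1 and 810 and 850 without replicate 2. The aged counts were 467 and 507 without aged spleen replicate 1, 443 and 580 without replicate 2, and 703 and 700 without aged muscle replicate 2. With the tested genes held, the young counts were 660 and 784, and 776 and 849, and the aged counts 426 and 444, 441 and 488, and 714 and 688. The tissue effects at the 2 ages correlated across genes with r of 0.58 and rho of 0.63. That r was 0.29 without young muscle replicate 2, 0.33 without aged muscle replicate 2 and 0.46 to 0.51 without any other library, or 0.37, 0.42 and 0.53 to 0.60 with the tested genes held. Genes higher in muscle at both ages numbered 734 against 161 for independent lists and genes lower at both ages 738 against 149, while 26 and 42 had opposite directions. These comparisons also share the spread of each gene, which the numbers for independent lists leave out.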

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

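The difference of the age effects between the tissues was a planned test, and the count of genes high in a pair of libraries was set before its result was seen. The other tests in this part were chosen after the result was seen. The division of the test on depth by group was also made after its values were seen; over all 32 genes together the share was 34.4%. The sums of myeloid markers replaced a test on their median, -0.09 between aged muscle and young muscle replicate 2. The myeloid, stromal and globin genes given by count were chosen after their values were seen. Each result here was picked because its age effect differed between muscle and spleen by the edgeR test of the difference itself or by camera on that difference.

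The age effect was higher in muscle for 199 genes and lower for 173. Median differences of the lists past the threshold were 1.09 for interferon response, 1.23 for naive and lymphoid residence, 0.26 for ribosomal proteins, -0.32 for Treg identity, -1.02 for tissue Treg, -0.54 for effector and co-inhibitory receptors, -0.11 for the IL-1 family and -2.95 for myeloid markers. Camera with an estimated correlation kept the call of the naive list alone (adjusted p = 0.017). With the preset correlation the myeloid call ended without young muscle replicate 1 (median -0.81), though not with the tested genes held (adjusted p = 0.044), the Treg identity call without aged spleen replicate 2, young muscle replicate 2 or aged muscle replicate 2, and the ribosomal call without young muscle replicate 2 or aged muscle replicate 1. With the tested genes held, the IL-1 family call also ended without young spleen replicate 2 (adjusted p = 0.053). Among single genes Zic1 differed by 6.79, Metap1d by 4.99, Dpf1 by 4.91, Kazald1 by 4.66, Flrt3 by 4.53 and Lmbr1 by 4.52 on the log2 scale. Gatm differed by 4.21, Treml2 by 4.17, Oas2 by 4.11, Maff by 4.06, Xist by 4.03 and Pgpep1 by 4.00. In the other direction Cd40lg differed by -8.31, Hdgfl1 by -4.60, Ankrd45 by -4.19, Sox9 by -4.18, Gpm6b by -3.88 and Arnt2 by -3.31. Dnm3os differed by -3.18, Angptl2 by -3.15, Trabd2b by -3.13, Itgae by -3.04, Baiap3 by -3.02 and Bmpr1a by -2.98.

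Interferon response genes were higher in aged than in young muscle. A rise carried by 1 library is argued against, since the aged library with the lower list median lay above the young library with the higher one by a median of 1.00 on the log2 scale, and 49 of 52 members were positive. The list median with age was 0.10 in spleen, with an upper quartile of 0.36, against 1.08 in muscle. Interferon exposure that raised the list alike in both tissues would not give these values. The list was picked here on its difference between the tissues, so they are no separate test of such exposure. Myeloid cells rich in interferon transcripts in the aged sort are argued against as the whole cause. The summed myeloid markers were at 2090 and 573 CPM in young and 505 and 506 in aged muscle, with the higher aged minus the lower young library at -67.7 CPM, while the interferon list rose by 3030 CPM or more. A smaller share, or cells without these markers, was not tested. An effect of age on Tregs of injured muscle may account for the rise and stays untested beyond these 4 libraries.

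Myeloid transcripts were higher in young than in aged muscle, although the cells had been sorted as Tregs. The median marker was 2.10 higher (log2) in young muscle replicate 1 than in replicate 2, and 23 of 24 markers were positive, which is consistent with myeloid cells or their RNA in that library. Lyz2 had 288 counts there and 24, 1 and 4 in the other muscle libraries, C1qa 275 against 0, 0 and 17, and Apoe 622 against 18, 11 and 56. Among the muscle libraries it also stood apart in some transcripts of other cells, so its excess was not myeloid alone. Col1a1 had 374 counts there against 30, 4 and 13, Pdgfrb 83 against 2, 1 and 1, and Hbb-b1 159 against 3, 7 and 6. In the spleen libraries Hbb-b1 had 200, 60, 542 and 812 counts, so that library did not stand apart in it across the series. Between the 2 young muscle libraries the median stromal and endothelial marker differed by 3.40, with 9 of 13 positive, the median erythroid marker by 0.60, with 6 of 11 positive, and the median muscle cell marker by -0.35. Whether both young muscle libraries also share a difference of age cannot be told apart from none, since replicate 2 lay only 0.09 above the aged mean with quartiles from -0.40 to 1.75. Tyrobp is also held by the CD8 T and NK cell list.

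Some genes were high in both libraries of a group and low in all other libraries, such as Zic1 with 563 and 609 counts in young spleen against 13 to 44 elsewhere. With a mean of at least 32 CPM and 4 times every other library, the replicate pairs gave 5, 6, 9 and 12 genes, while the highest of 24 pairs of libraries of different groups gave 1, which argues against independent amplification noise in single libraries as the cause. Besides Zic1, genes named above for large age effects that met this rule included Gatm, Kazald1, Kit, Sall3, Nr5a2, Ccdc63, Bzrap1, Smc1b and Fgd1. Flrt3, Dnm3os, Baiap3 and the clone-named AC137902.1 and RP23-159J2.2 met it as well. So did Rsad2 of the interferon list, with 172 and 140 counts in aged muscle against 11 to 46 elsewhere. High in 1 library alone were 46 genes in young muscle replicate 1 and 9 in aged muscle replicate 2. Reads added to both libraries without regard to depth are argued against in aged spleen, where 0% of 6 genes (exact 95% interval up to 45.9%) had raw counts nearer to equal than to the depth ratio, against 18.8% of other genes. The share was 40% of 5 genes in young spleen (5.27 to 85.3%, other genes 31.2%), 66.7% of 9 in young muscle (29.9 to 92.5%, other genes 23.8%) and 25% of 12 in aged muscle (5.49 to 57.2%, other genes 26.8%). In young muscle the interval lay above the share of other genes, so its 9 genes, Sall3 and Nr5a2 among them, leaned toward equal raw counts. In young spleen and aged muscle the interval held the share of other genes. The genes are too few to decide, so added reads and true expression cannot be told apart in those 3 groups. A state of the Tregs of that age and tissue and a shared origin of the 2 libraries of a group both remain possible, because group and origin coincide in this design.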

How the results depend on the processing

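Scaling by library size alone, list counts without single libraries, and refits without a library on the same 14772 genes were added after seeing the data. Fitting all genes with a count gave 417 higher and 331 lower for age in muscle and 632 and 407 for age in spleen. For the difference of age effects it gave 299 higher and 371 lower. DESeq2 gave 243 higher and 254 lower for age in muscle. Fitting only the 2 groups compared leaves fewer libraries to estimate the spread. It gave 33 and 17 for age in muscle and 928 and 1002 for age in spleen. The SD across genes of the log2 difference between the 2 libraries was 1.04 in young and 0.826 in aged muscle. In young and aged spleen it was 0.721 and 0.635, while the main fit shared 1 spread among the groups. Numbers of calls in the 2 tissues are therefore not directly comparable, and p-values for muscle may be too small. Scaling by library size alone gave 489 higher and 236 lower for age in spleen. It moved the median of all genes by 0.119 for age in muscle, 0.165 for age in spleen and 0.114 for tissue in young mice. The labels do not pair libraries of equal replicate number. Deviations of same-numbered libraries correlated between -0.07 and 0.26, the highest between young and aged muscle. Such values cannot tell whether those libraries shared an animal, sort or batch. With replicate numbers as a block, age in muscle gave 263 higher and 216 lower and age in spleen 469 and 424. With an estimated correlation 0, 1, 1, 2 and 0 gene lists passed, in the order age in muscle, age in spleen, difference, tissue in young and tissue in aged. By fry 2, 7, 5, 10 and 9 passed in that order. The correlation of tissue effects was 0.67 with a mean of at least 10 CPM.

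With 1 library left out, which raised the genes tested to between 15836 and 16728, age in muscle ranged from 102 to 586 higher and 51 to 481 lower, age in spleen from 82 to 596 and 62 to 460, and the difference from 82 to 298 and 77 to 391. Tissue in young mice ranged from 675 to 1884 and 808 to 1787, and tissue in aged mice from 443 to 2003 and 507 to 1959. Gene lists passing ranged from 2 to 11, 8 to 12, 8 to 12, 9 to 15 and 5 to 11 in the same order. The correlation of age effects ranged from -0.03, without aged muscle replicate 2, to 0.18, and that of tissue effects from 0.29 to 0.51. With the tested genes held the ranges were 98 to 553 and 46 to 425, 74 to 567 and 60 to 479, 71 to 298 and 66 to 348, 660 to 1891 and 784 to 1787, and 426 to 2079 and 444 to 1873 in the same order. Gene lists then ranged from 2 to 9, 8 to 12, 7 to 12, 10 to 15 and 7 to 11, and the correlations from -0.01 to 0.20 and 0.37 to 0.60. Of 581 changes of call of named genes without a library, 543 recurred with the tested genes held. Of 8819 values of named genes under an alternative, 7995 kept their side of the threshold, 518 lost and 306 gained the call. None of the values called in the main fit or the alternative changed sign. The sign of values called in neither was not checked. The causes of these moves were not tested beyond the genes held. Depth limits genes under about 0.67 CPM.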

Other observations

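Stress and early response genes separated Tregs of muscle from those of spleen in both directions. Of 39 measured members, 18 were higher and 14 lower in young muscle, and 20 higher and 9 lower in aged muscle. Fosb, a component of the AP-1 transcription factor, was higher by 3.71 ± 0.19 in young and 2.93 ± 0.18 in aged mice. The list passed camera in aged mice (adjusted p = 0.00924, adjusted p = 0.61 with an estimated correlation) and not in young mice (adjusted p = 0.248). The call in aged mice ended without either aged spleen library, young muscle replicate 1 or aged muscle replicate 1, but with the tested genes held it ended only without aged spleen replicate 1.

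Homing and effector genes also differed by tissue. Of 25 homing genes 15 were higher and 7 lower in young muscle, and 14 higher and 4 lower in aged muscle (adjusted p = 0.28 and 0.54 with an estimated correlation). Of 20 effector genes 11 were higher and 3 lower in young muscle, with Fgl2 at 3.49 ± 0.23 (adjusted p = 0.16 with an estimated correlation). The monocarboxylate transporter gene Slc16a3 was higher by 3.38 ± 0.28 among 8 of 25 glycolysis genes higher in young muscle, a list that did not pass camera (adjusted p = 0.054). Of 22 cell cycle inhibitors and p53 targets 8 were higher and 3 lower in young muscle, with Gadd45b at 3.03 ± 0.17 (adjusted p = 0.33 with an estimated correlation), and that list did not pass without young muscle replicate 1 or either aged muscle library, though it passed in all 3 cases with the tested genes held. Of 50 G2/M genes 9 were higher and 1 lower in young muscle (camera adjusted p = 0.0333, adjusted p = 0.82 with an estimated correlation), and 3 and 2 without young muscle replicate 1, where the list no longer passed camera, nor did it without young spleen replicate 1. Glycolysis passed without young spleen replicate 2 or young muscle replicate 2.

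Lists that passed camera in neither age comparison included homing genes with medians of -0.38 in muscle and 0.26 in spleen (camera direction down in spleen, mean 0.03), growth and repair factors at 0.01 and -0.02 (means -0.35 and 0.32), G1/S genes at 0.01 and 0.11, apoptosis regulators at -0.15 and -0.04 and glycolysis at -0.08 and 0.16. B cell markers stood at 0.24 and 0.88, muscle cell markers at 0.22 and 1.06, stromal and endothelial markers at -1.12 and -0.94, CD8 T and NK cell markers at 0.17 and 0.18, G2/M genes at -0.23 and 0.01, cell cycle inhibitors at -0.19 and -0.15, and stress and early response genes at -0.04 and -0.20. Some of these lists passed without single libraries, such as stromal and endothelial markers in muscle without young muscle replicate 2 or aged muscle replicate 2. In muscle naive genes stood at -0.09, effector genes at 0.25, IL-1 family genes at 0.26, helper lineage genes at 0.30, lipid synthesis genes at -0.10 and erythroid markers at 0.67 (mean -0.80), and in spleen oxidative phosphorylation at -0.07 and myeloid markers at 0.68, none past camera.

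Xist, which silences an X chromosome in female cells and overlaps the antisense gene Tsix, had 102 and 115 counts in young spleen, 21 and 22 in aged spleen, 23 and 22 in young muscle and 57 and 56 in aged muscle, in mice labelled male. The Y-linked gene Ddx3y was read in all 8 libraries.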
